A study of Mus musculus with 6 samples.

How the data were processed

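Total RNA from the quadriceps muscle of NOD-SCID mice, a strain without functional T and B lymphocytes, was hybridised to Illumina MouseWG-6 v2.0 arrays per the labels' design text. Each mouse had carried subcutaneous RXF393 or SKRC39 human renal cancer cells for 22 days. The labels describe RXF393 as cachectic and SKRC39 as not. The design text gives 3 mice, without saying whether per line, and 6 RNA samples with RNA extracted mouse by mouse. This is read here as 3 mice per line and 1 mouse per array, and on that reading the p-values measure spread between separate mice.

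The labels disagree on 2 of the 6 arrays. The array titled RXF_1 is described in its source name and characteristics as SKRC39, and the array titled SKR_3 as RXF393. These 2 arrays were assigned to no group and entered no main comparison. The 4 arrays whose title, source name and characteristics name the same line were compared: SKRC39 replicates 1 and 2 against RXF393 replicates 2 and 3, numbered by title. Both ways of grouping all 6 arrays were run as alternatives. Every comparison, gene list and naming rule was fixed before the data were examined, as was every alternative but one, the axis built without each array. Some tests of the closing section were set down later, as stated there.

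The first deposited table holds non-normalized probe intensity on a linear scale and a detection p-value per probe and array, per the file headers. The authors' second table holds intensity after quantile normalization in the GenomeStudio Gene Expression module 1.9.0, per the labels' design text and the submitters' processing notes. Its array medians lie between 135.29 and 135.42. Of 45281 probes, 34885 carry 1 gene symbol in the platform annotation, 18 carry several and 10378 are not listed there and stay unnamed here. By gene ID, 34807 of the probes with 1 symbol were matched to the RefSeq table for GRCm38.p6, and no symbol changed. No genome build is given in the sources used here for the array files, so no coordinates are printed.

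Intensities were corrected for background by normexp, with the negative-control distribution inferred from the detection p-values, quantile-normalized over the 6 arrays with an offset of 16 and taken to log2 (neqc in limma 3.58.1, R 4.3.3). The offset makes fold changes of dim probes too small. Probes with a detection p below 0.05 on at least 2 arrays were kept, which left 17738 probes and 10196 named genes. limma's moderated test (lmFit, eBayes with an intensity trend) was adjusted by Benjamini-Hochberg over all probes tested, with a threshold of 0.05. A gene is represented by its probe with the highest mean over the 6 arrays. Of the 14 genes past the threshold that had more than 1 tested probe, 13 had all probes in one direction, the exception being Smtn, and 3 had all probes past the threshold.

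A probe not detected on either array of a group has only a bound there. Its fold is given as "at least", from the mean of the brighter group against the mean of the higher of the dim probe's value and the lowest detected value on each array. The same bound is used where 1 of the 2 arrays of the dimmer group detected the probe. The same wording is used where the brighter group lies within 20% of the highest signal on both arrays. The number of arrays limits the precision of every value.

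Named genes were chosen by rule. Among genes past the threshold whose 2 arrays of one group both lay above both arrays of the other, these are the 12 with the largest positive and the 12 with the largest negative change, clone-only symbols being skipped. From each gene list, up to 3 members past the threshold were added. Always given are Fbxo32, Trim63, Foxo1, Foxo3, Cpt1b, Pdk4, Ppargc1a, Mstn, Myh4 and Myh7. Mstn was below the detection filter and was not tested.

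Shifts of 37 gene lists, 860 entries of which 665 were tested, were examined with camera at a preset inter-gene correlation of 0.01. Benjamini-Hochberg adjustment ran over the lists. camera with an estimated correlation and fry were alternatives. Other alternatives changed the background correction, the scaling, the filter, the treatment of a gene's probes, the variance model, the threshold, the arrays and the pairing. The arrays with conflicting labels were placed on an axis from the SKRC39 mean (0) to the RXF393 mean (1), averaged over the 100 probes with the smallest p in each direction. This placement was never used to assign a group.

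The fits were tested on simulated data drawn from the real probes' means and limma's moderated variances, with 200 of 17738 probes changed. For 2 against 2 arrays, 40 of 40 probes changed 32-fold were recovered, 24 of 40 changed 8-fold, 7 of 40 changed 4-fold and 1 of 40 changed 2-fold. Over 20 such draws, 14.5% of the probes past the threshold were unchanged ones, which is above the rate that the threshold of 0.05 stands for. For 3 against 3 arrays the share was 9.79%. In the simulation a list of 30 probes shifted by 0.5 on the log2 scale passed camera, and 0 of 50 unshifted lists did. The draws used the probes' means and moderated variances, normal noise and no correlation between genes. The simulation therefore cannot show how camera behaves for lists of correlated genes. Nor can it show the share of unchanged probes past the threshold where arrays differ over many genes together.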

Results

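Gene expression was measured in quadriceps muscle of mice carrying RXF393 cells, described in the labels as cachectic, or SKRC39 cells, described as not cachectic. Cachexia is the loss of muscle and fat that accompanies some tumours, and the comparison asks how muscle differs between the 2 tumour lines. Titles and characteristics name the same line on 4 of the 6 arrays, 2 per line. Detected probes made up 37.7% and 33.7% of all probes on SKRC39 replicates 1 and 2, and 33.7% and 30.9% on RXF393 replicates 2 and 3. Over 2596 genes with 2 probes detected on both SKRC39 arrays, the changes of both probes against the SKRC39 mean were correlated. The values were 0.448 on RXF393 replicate 3 and 0.802 on RXF393 replicate 2. They were 0.495 and 0.516 on the arrays titled RXF_1 and SKR_3, whose labels conflict. On RXF393 replicate 3, 98 of 1718 pairs with a change over 2-fold had both probes changed that much in opposite directions. The counts were 0 of 656 on RXF393 replicate 2, 77 of 1670 on SKR_3 and 1 of 121 on RXF_1. Between the 2 SKRC39 arrays (replicate 2 minus replicate 1) the correlation was 0.238 and the count 29 of 820, so probes disagreed within that line too. The array titled RXF_1 changed little, so its correlation is not comparable. Unless all 6 arrays are named, all comparisons below set the 2 arrays of each line whose labels agree against each other. They give the log2 change of RXF393 against SKRC39 with its standard error (SE).

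In muscle of RXF393-bearing mice, 20 genes were higher and 16 lower than with SKRC39. The genes that rose most included acute-phase and stress-response genes. Lcn2, which encodes the iron-siderophore-binding protein lipocalin 2, rose by 6.69 ± 0.66 (SE, n = 2 per group; 103-fold), and Mt2, a metal-binding metallothionein, by 5.99 ± 0.61 (63.7-fold). Serpina3n, an acute-phase protease inhibitor, rose by 4.43 ± 0.51 (21.5-fold), and Socs3, a feedback inhibitor of JAK-STAT signalling, rose by 3.70 ± 0.44. Ddit4, an inhibitor of mTORC1, rose by 4.83 ± 0.38 (28.5-fold), from a mean log2 intensity of 9.04 ± 0.04 (SD, n = 2) to 13.87 ± 0.08. Depp1, a FoxO-responsive gene, rose 34.3-fold, and Sema5a, a semaphorin, 44.9-fold. Another tested Sema5a probe, at 0.84, did not pass (adjusted p = 0.56, limma).

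Other genes that rose act in signalling, transport and metabolism. Itpkc, an inositol trisphosphate kinase, rose 22.5-fold and Slc10a6, a transporter of sulfated steroids, 21.5-fold. Another tested Slc10a6 probe, at 1.80, did not pass (adjusted p = 0.39, limma). Ampd3, an AMP deaminase, rose 21.3-fold and Spsb1, a SOCS-box adaptor of ubiquitin ligases, 21.0-fold. Mustn1, a nuclear protein of the musculoskeletal system, was at least 9.18-fold higher, because both RXF393 arrays lay near the top of the signal range. Pnpla2, the adipose triglyceride lipase, rose by 1.84 ± 0.24 (3.57-fold). Its inhibitor G0s2 moved the other way and was 23.9-fold lower.

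The genes that fell most include several with known roles in muscle fibres. Aqp4, a water channel of the fast-fibre membrane, was not detected on either RXF393 array and was at least 45.3-fold lower (adjusted p = 0.0300, limma). Sypl2, a protein of the junction between transverse tubule and sarcoplasmic reticulum, was lower by a log2 change of -5.20 ± 0.37 (36.8-fold) on its main probe. Its 2 other tested probes stood at -1.98 and -0.73 and did not pass (adjusted p = 0.33 and 0.52, limma). Ky, a protease-like protein needed for muscle maintenance, was 21.9-fold lower, Mettl21c, a muscle lysine methyltransferase, 35.0-fold, and Myoz3, a Z-disc protein, 13.6-fold. Igfbp5, a binding protein of insulin-like growth factors, was 12.3-fold lower on its main probe, and its 3 probes all passed the threshold. Lrrc38, an auxiliary subunit of potassium channels, was detected on 1 of the 2 RXF393 arrays and was at least 41.1-fold lower (adjusted p = 0.0437). Nrep fell 38.5-fold, Fam78a 23.9-fold, the scaffold gene Mpp3 23.0-fold and the secreted-protein gene Wfdc1 11.8-fold. Another tested Ky probe at -0.52 and another Mpp3 probe at -3.79 did not pass (adjusted p = 0.55 and 0.14, limma).

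**Figure D1:**
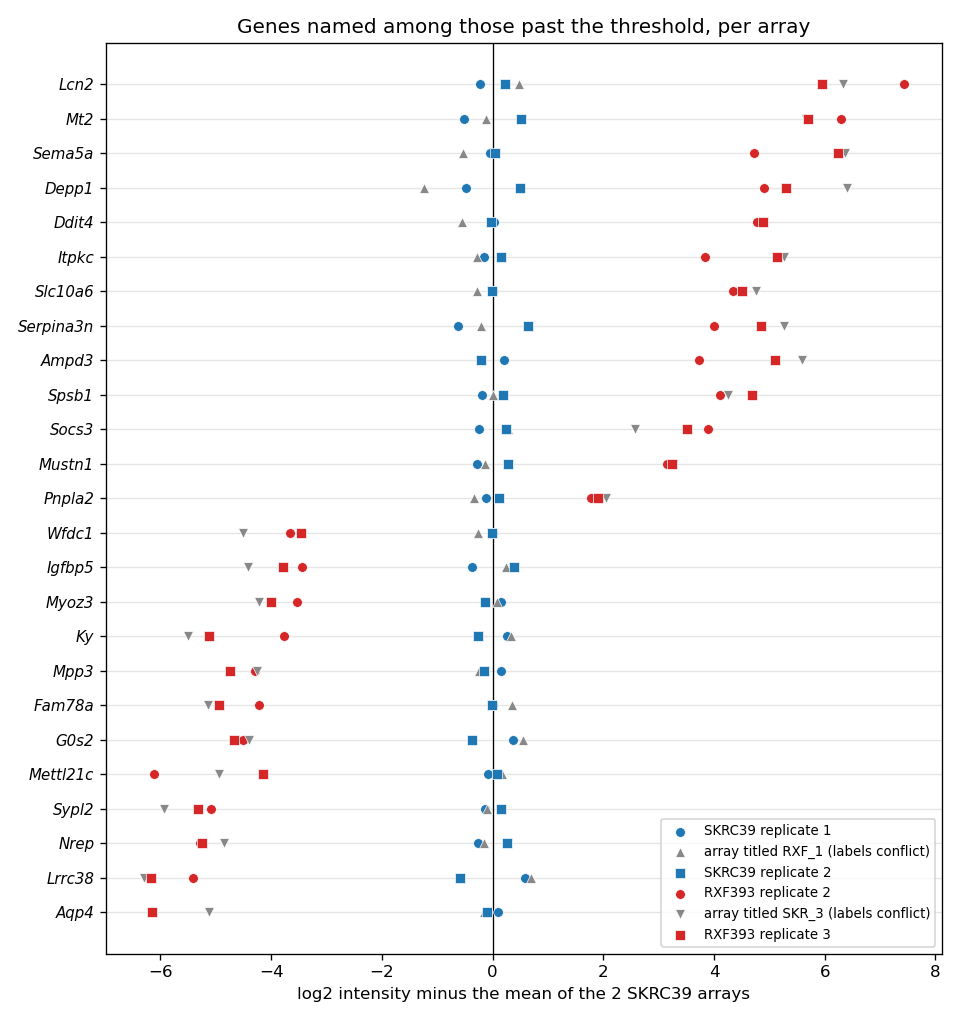
Log2 intensity of each named gene past the threshold (rows) on each array, minus the mean of the 2 SKRC39 arrays. Blue points are SKRC39 arrays, red points RXF393 arrays and grey triangles the 2 arrays with conflicting labels. Lcn2 lies 6.69 log2 units higher on average in RXF393 and Aqp4 is not detected there.

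Adjusted p-values of the named genes past the threshold ran from 0.0212 to 0.0497 in limma's moderated test. In simulated data of this size, with no correlation between genes, 14.5% of the probes past the threshold were unchanged ones. The share in the real data is not known. All 36 genes had non-overlapping groups, which chance gives for 33.3% of genes at 2 against 2 and which held for 48.7% of all genes tested. At an unadjusted p under 0.05, 826 genes were higher and 682 lower. The remaining genes past the threshold, named here after their values were seen, were Cnksr1, Atp6v1h, Rgcc, Mknk2, Tango2, Retreg1 and Impact among those higher, and Mef2c, Pgm1, Smtn and Sobp among those lower. The counts depended on the processing: 0 genes passed with median scaling in place of quantile scaling (1536 at an unadjusted p under 0.05) and 0 without the intensity trend (1350), whereas grouping all 6 arrays by characteristics gave 1868 and by title 0 (19 at an unadjusted p under 0.05). Without SKRC39 replicate 1, 45 genes were higher and 20 lower, without SKRC39 replicate 2 the counts were 74 and 60, without RXF393 replicate 2 they were 173 and 277, and without RXF393 replicate 3 they were 6 and 14. Among the 25 named genes past the threshold, those that lost their call when 1 array was left out were mostly higher ones. They were Mt2, Sema5a, Itpkc, Slc10a6, Serpina3n, Ampd3, Spsb1, Socs3 and Pnpla2 among those higher, and Lrrc38 and G0s2 among those lower. These fits leave 1 array in a group. The folds of 8 named genes moved by over 1.5 times: Lcn2 (62.0 to 173), Sema5a (26.5 to 76.0), Itpkc (14.4 to 35.2), Serpina3n (13.9 to 33.3), Ampd3 (13.3 to 34.1), Mettl21c (17.7 to 68.9), Ky (13.7 to 35.0) and Lrrc38, whose fold is only a bound.

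The gene lists are described next. With a preset correlation 7 lists rose and 6 fell, but with an estimated correlation none of the 37 lists passed (lowest adjusted p = 0.42), and none passed fry (lowest adjusted p = 0.0706). The preset test also called 7 lists higher and 5 lower when the 6 arrays were grouped by title, a grouping in which 0 genes passed. That grouping keeps the 4 concordant arrays with the same labels, so part of the main difference stays in it. These calls therefore cannot show how often the test calls lists where there is no difference.

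The list of the IL-6, STAT3 and NF-kB inflammatory response rose (adjusted p = 2.08e-07, camera; adjusted p = 0.42 with an estimated correlation). Of its 28 tested genes, 3 rose (Lcn2, Serpina3n and Socs3), 0 fell and 25 did not pass. Adjusted over the list alone, 11 rose, among them the transcription factor gene Cebpd at 3.13 ± 0.64 and the acute-phase gene Saa3, which was not detected on either SKRC39 array and was at least 10.2-fold higher (adjusted p = 0.00658 over the list alone). Immediate early and stress kinase genes rose as a list (adjusted p = 2.14e-05; adjusted p = 0.42 with an estimated correlation). None of its 24 genes passed over all genes, and 9 did adjusted over the list alone, including Fos at 4.07 ± 0.76, Atf3 at 3.27 ± 0.60 and Zfp36, whose product destabilises cytokine mRNA, at 3.57 ± 0.51. Neutrophil markers were higher as well (adjusted p = 9.49e-05; adjusted p = 0.42 with an estimated correlation), Lcn2 being the only one of 7 to rise over all genes tested, with S100a8 (3.47 ± 0.74), S100a9, Retnlg and Chil3 also past the threshold adjusted over the list alone; Retnlg and Chil3 were not detected on either SKRC39 array. Of the neutrophil list's 14 members only these 7 were tested, and Lcn2 is also a member of the inflammatory list. The neutrophil list did not pass by title (adjusted p = 0.28, camera). On RXF393 replicates 2 and 3 the neutrophil list's median, relative to each gene's mean over the 6 arrays, was 0.45 and 2.31, and on SKRC39 replicates 1 and 2 it was -2.05 and -1.15. Erythroid markers rose (adjusted p = 0.00711; adjusted p = 0.58 with an estimated correlation), none of 6 passing over all genes; Slc4a1 (3.65 ± 0.67) and Alas2 (2.61 ± 0.53) passed adjusted over the list alone. The list did not pass without SKRC39 replicate 2 (adjusted p = 0.0694) or by characteristics with the description number as a block (adjusted p = 0.0585).

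Genes of the FoxO and glucocorticoid response rose as a list (adjusted p = 1.46e-09; adjusted p = 0.42 with an estimated correlation). Ddit4 and Mt2 rose among 22 genes, 0 fell, and 14 rose adjusted over the list alone, including the cell-cycle inhibitor Cdkn1a at 3.70 ± 0.51, Sesn1 at 4.12 ± 0.62 and the glucocorticoid-induced Fkbp5 at 3.10 ± 0.47. Foxo1 stood at 1.84 ± 0.54, and Foxo3, detected on 1 of the 2 SKRC39 arrays, had means at least 4.65-fold apart; neither passed over all genes (adjusted p = 0.26 and 0.28, limma). Proteasome subunits rose (adjusted p = 1.69e-08; adjusted p = 0.42 with an estimated correlation), with a positive change in 26 of 28, none past the threshold over all genes and 9 adjusted over the list alone, such as Psmc4 at 1.72 ± 0.32 and Psmd14 at 2.00 ± 0.49. Heat shock proteins rose (adjusted p = 0.0181; adjusted p = 0.42 with an estimated correlation), and of 14 genes none passed over all genes and 1, Hspb1 (1.60 ± 0.34), adjusted over the list alone. The heat shock list did not pass with all 6 arrays grouped by characteristics (adjusted p = 0.12, or 0.0961 with the block), without the intensity trend (adjusted p = 0.0688) or without RXF393 replicate 2 (adjusted p = 0.20). The list of atrophy ubiquitin ligases and other atrogenes did not pass (adjusted p = 0.0509), with none of 17 genes past the threshold over all genes and 2, Eif4ebp1 and Fbxo31, adjusted over the list alone. This miss is not firm: the list passed in 10 alternatives, with adjusted p-values from 6.47e-04 without RXF393 replicate 3 to 0.0496 with offset 50, by title among them (adjusted p = 0.0473), but not by characteristics (adjusted p = 0.15) or with an estimated correlation (adjusted p = 0.43). Of the ligases known as muscle atrophy markers, Trim63 stood at 2.16 ± 1.15 (adjusted p = 0.47) and Fbxo32 at 1.28 ± 0.45 (adjusted p = 0.33). On average 1 of the 3 Fbxo32 probes moved the other way, because of RXF393 replicate 3. That probe stood at 13.94 and 8.25 on RXF393 replicates 2 and 3, and at 12.70 and 10.50 on SKRC39 replicates 1 and 2. On the arrays titled SKR_3 and RXF_1, whose labels conflict, it stood at 8.58 and 11.69. Leaving out one array gave 0.27 to 4.06 for Trim63, which stood at 11.15 and 7.36 on the 2 SKRC39 arrays, and 0.56 to 2.01 for Fbxo32. Neutrophil markers were higher alongside these lists, with a median log2 change of 2.68, and RXF393 replicate 3 had the lowest share of detected probes of the 4 arrays, 30.9%.

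Oxidative phosphorylation genes fell as a list (adjusted p = 1.22e-10; adjusted p = 0.42 with an estimated correlation), with a negative change in 60 of 66 genes, a median log2 change of -0.53 and none past the threshold, over all genes or adjusted over the list alone, and with 6 near the top of the signal range on all 4 arrays; Uqcrc1 of complex III stood at -1.23 ± 0.32. The TCA cycle and pyruvate dehydrogenase list fell (adjusted p = 9.91e-04; adjusted p = 0.42 with an estimated correlation), with Idh3a (-1.92 ± 0.38) and Dlat (-1.90 ± 0.45) the 2 of 21 that passed adjusted over the list alone; it did not pass by title (adjusted p = 0.19). Glycolysis and glycogen genes fell (adjusted p = 0.00520; adjusted p = 0.63 with an estimated correlation): of 21 genes, 4 were lower adjusted over the list alone, including Pkm (-2.40 ± 0.63), and Ugp2, which makes UDP-glucose, was higher (1.39 ± 0.26). That list did not pass under median scaling (adjusted p = 0.0534), without the intensity trend (adjusted p = 0.0666), without RXF393 replicate 3 (adjusted p = 0.0947) or by title (adjusted p = 0.90). Fatty acid oxidation genes did not pass as a list (adjusted p = 0.97), the median change of 0.03 and the direction of the test differing in sign; the list's only member past the threshold adjusted over the list alone was the acyl-CoA thioesterase Acot1 at 4.24 ± 0.65. In the list of fatty acid uptake, storage and lipolysis (adjusted p = 0.29), Pnpla2 rose and G0s2 fell among 22 genes, and Plin5, Mlycd and Pdk4, an inhibitor of pyruvate dehydrogenase at 2.30 ± 0.58, passed adjusted over the list alone. Cpt1b, the muscle carnitine palmitoyltransferase, stood at -0.47 ± 0.31 and the coactivator Ppargc1a at -0.41 ± 0.54. Leaving out one array gave 1.45 to 3.15 for Pdk4, -0.69 to -0.25 for Cpt1b and -0.81 to -0.01 for Ppargc1a. The PPAR and PGC-1 regulators did not pass as a list (adjusted p = 0.34), although 4 of 14 were lower adjusted over the list alone, including Perm1 at -2.34 ± 0.33. Beside these lists, fibroblast markers had a median log2 change of -1.37, and RXF393 replicate 3 had the lowest share of detected probes of the 4 arrays, 30.9%.

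Fast-fibre contractile genes fell as a list (adjusted p = 0.0219; adjusted p = 0.42 with an estimated correlation), with a median log2 change of only -0.12 and Myoz3 the only one of 20 genes past the threshold over all genes or adjusted over the list alone. On all 4 arrays 9 of the 20 lay near the top of the signal range, where a change can be hidden, and the list did not pass under median scaling (adjusted p = 0.21), without the intensity trend (adjusted p = 0.0834), without RXF393 replicate 2 (adjusted p = 0.0585) or by title (adjusted p = 0.74). The fast myosin heavy chain Myh4 stood at -0.11 ± 0.25. The slow chain Myh7 was detected on 1 of 2 arrays of each line, so its value of 0.04 ± 0.43 lies at background and does not measure a change. Extracellular matrix genes fell (adjusted p = 9.49e-05; adjusted p = 0.51 with an estimated correlation). None of 24 passed over all genes, 8 fell adjusted over the list alone, including Sparc (-3.62 ± 1.16) and Col1a1, which was detected on 1 of the 2 RXF393 arrays and was at least 5.50-fold lower (adjusted p = 0.0395 over the list alone), and Lox, the collagen cross-linking enzyme, was higher (2.12 ± 0.61). The matrix list did not pass among probes detected on all 6 arrays (adjusted p = 0.0711). Fibroblast and mesenchymal progenitor markers, which share members with that list, fell too (adjusted p = 2.14e-05; adjusted p = 0.42 with an estimated correlation), all 14 with a negative change, and Col1a1 and Fmod past the threshold adjusted over the list alone, Fmod not being detected on either RXF393 array. The fibroblast list's median, relative to each gene's mean over the 6 arrays, was -0.01 and 0.91 on SKRC39 replicates 1 and 2 and -0.74 and -0.51 on RXF393 replicates 2 and 3, and its change was -0.79 without SKRC39 replicate 2.

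**Figure D2:**
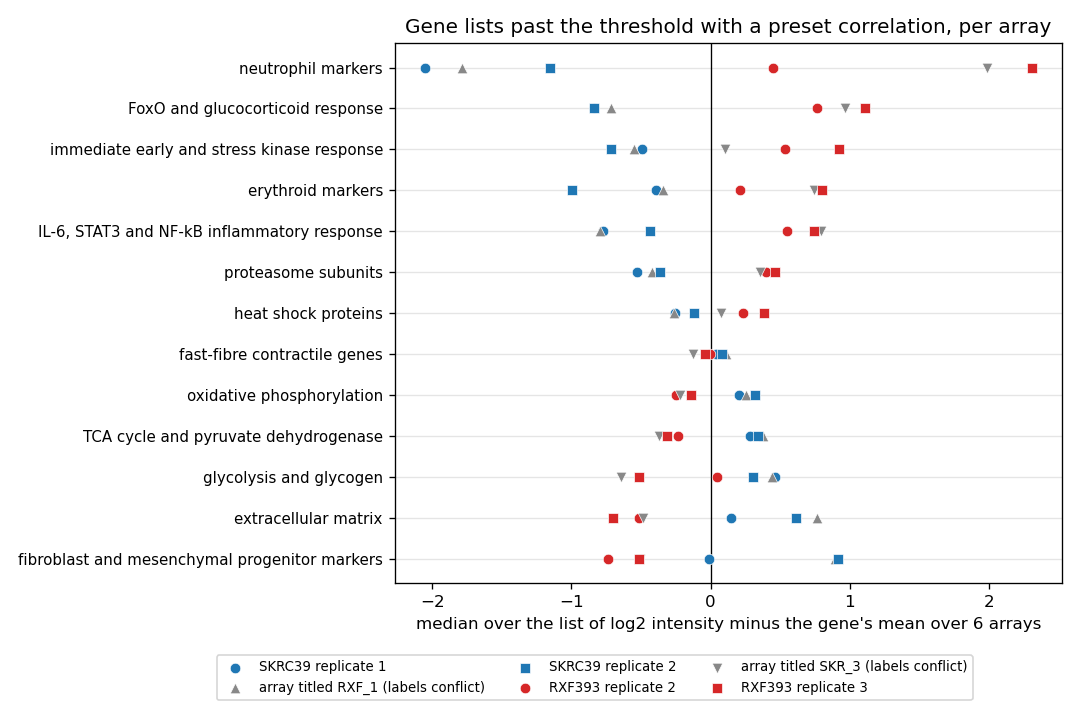
Median over each gene list past the threshold (rows) of log2 intensity minus the gene's mean over the 6 arrays, for each array. Blue points are SKRC39 arrays, red points RXF393 arrays and grey triangles the 2 arrays with conflicting labels; oxidative phosphorylation genes were at 0.21 and 0.32 on the SKRC39 arrays and at -0.25 and -0.14 on the RXF393 arrays.

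No other list passed in the main fit. The adjusted p from camera was 0.0808 for slow-fibre contractile genes (8.13e-07 by title, 0.82 by characteristics), 0.0785 for adipocyte markers, 0.15 for autophagy and lysosome, 0.17 for the interferon response, 0.21 for ribosome biogenesis, 0.25 for macrophage markers, 0.30 for antioxidant genes and 0.31 for the cell cycle. It was 0.34 for the circadian clock, 0.39 for Schwann cell markers, 0.46 for denervation genes, 0.49 for the integrated stress response, 0.53 for amino acid metabolism, where Ampd3 rose, and 0.53 for smooth muscle markers, where Mustn1 rose. For insulin, IGF and mTOR signalling it was 0.62, with Ddit4 higher and Igfbp5 lower. It was 0.73 for keratinocyte markers, 0.77 for satellite cells, 0.82 for TGF-beta signalling, 0.82 for endothelial markers and 0.82 for lymphoid markers. The median and the test differed in sign for satellite cells and for insulin, IGF and mTOR signalling. Several of these misses depended on one array. Without RXF393 replicate 3 the lists of slow-fibre genes and adipocyte markers passed as lower (adjusted p = 1.35e-04 and 0.0328), and those of autophagy, denervation, antioxidant, ribosome biogenesis and fatty acid uptake genes as higher (adjusted p = 0.00966, 0.0108, 0.0268, 0.0114 and 0.00200). Without SKRC39 replicate 1, adipocyte and macrophage markers passed as lower (adjusted p = 1.43e-04 and 0.0197) and ribosome biogenesis as higher (adjusted p = 0.0351). With no filter on dim probes, slow-fibre genes and adipocyte markers passed (adjusted p = 0.0261 and 0.0492).

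On the axis from the SKRC39 mean (0) to the RXF393 mean (1), the array titled RXF_1 lay at -0.0192 and the array titled SKR_3 at 1.15. The 4 concordant arrays, from which the axis was built, lay at -0.0253 and 0.0253 for SKRC39 and at 0.917 and 1.08 for RXF393. No p-value is given for these positions.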

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

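Each test here was set down before its own result was seen, but those on RXF393 replicate 3 and on the title number were set down after the correlations between arrays and the Fbxo32 probes had been seen, and that of the probe difference shared with the SKRC39 arrays and the axes built without one array came after the other results. The array titled SKR_3, which was left out of the main comparison, lay at 1.15 on the axis from SKRC39 (0) to RXF393 (1), above both SKRC39 arrays. A signal in an array that the main comparison did not use is what singled it out.

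The pattern weighed first is that 2 arrays have labels naming different lines. If the titles were right, the array titled RXF_1 should lie above 0.5 and that titled SKR_3 below it, but they lay at -0.0192 and 1.15, on the opposite sides. The pooled SD of 0.0868 comes from the arrays that built the axis, but with each of these left out in turn the 2 arrays lay at -0.0205 to 0.102 and 0.991 to 1.16, still further from 0.5 than the pooled SD of 0.302 of the left-out arrays (0.0212 and 0.310 for SKRC39, 0.522 and 1.05 for RXF393), which argues against the titles for both and goes with the characteristics, so a swap in the titles is a candidate explanation. Another reading is that the titles were right and an effect shared by arrays of one title number hid the line. With the title number as a block, the titles called 0 genes (143 at an unadjusted p under 0.05). The characteristics called 1868 with no block and 3114 with the description number as a block. This argues only against a line effect by title large enough to pass, and a weaker one stays open. On the first principal component (75.1% of the variance) the arrays followed title number. They lay at -107 and -87.3 for number 1, -35.95 and -10.4 for 2, and 119 and 122 for 3. This order parts the lines of the characteristics as well. The main comparison and the axis set numbers 1 and 2 against 2 and 3, so both are partly confounded with title number. Whether RNA quality, which also sets arrays apart, adds to the positions stays open too. The positions come from gene values and do not settle the label.

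Grouped by characteristics, 1868 genes passed, and the highest count among the other splits of the 6 arrays into 3 and 3 was 0, so 1 of 10 splits gave as many. Grouped by title, 0 genes passed, so 10 of the 10 splits gave as many, and the highest other count was 1868. With 10 splits the share is never under 0.1, too few to test chance.

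The pattern weighed second is that RXF393 replicate 3 stood apart from RXF393 replicate 2. Its distance from the SKRC39 mean was 1.56 times that of replicate 2 over probes detected on all 6 arrays and 1.77 times under median scaling, which argues against fewer detected probes and quantile scaling as the cause. The array titled SKR_3 lay as far from the SKRC39 mean as replicate 3. The distances were 1.342 and 1.331 over those probes and 1.501 and 1.499 under median scaling. If that array is RXF393, as its characteristics say, replicate 2 is the RXF393 array that differs. The 2 probes' changes were correlated over 2596 pairs of probes of one gene (Fbxo32 left out, its probes having been seen). The correlation was 0.448 for replicate 3 and 0.802 for replicate 2. The difference was -0.354 (bootstrap interval -0.387 to -0.318, across genes and not between mice). Signal lost unevenly along transcripts would lower the correlation in this way. The positions of the probes along transcripts were not used, so the value cannot tell such loss from other disagreement between probes. At 0.516 for the array titled SKR_3, a low value is not particular to replicate 3. Between the 2 SKRC39 arrays (replicate 2 minus replicate 1) the correlation was 0.238. The value of 0.495 for the array titled RXF_1 is not comparable, because that array changed little. It had 121 pairs with a change over 2-fold, against 1718 for replicate 3 and 1670 for the array titled SKR_3. The difference between the 2 probes in replicate 3 correlated at 0.613 (0.582 to 0.641, across genes) with that between the 2 SKRC39 arrays (replicate 2 minus replicate 1), against 0.160 for RXF393 replicate 2, 0.588 for the array titled SKR_3 and -0.518 for that titled RXF_1, so the property varies within SKRC39, and whether it also goes with the tumour line or the labels stays open. A stronger response of that mouse to its tumour stays open and was not tested.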

How the results depend on the processing

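All of these alternatives were planned, except the axis built without each array in turn, which was chosen after seeing the data. Against 20 genes higher and 16 lower, normexp with offset 50 gave 10 and 9, the deposited normalized values 12 and 12, the mean of a gene's probes 12 and 10, median scaling 0 and 0 (1536 genes at an unadjusted p under 0.05 in limma) and eBayes without an intensity trend 0 and 0 (1350). The robust variance model gave 47 and 41, probes detected on all 6 arrays at 0.01 gave 104 and 64 from 9512 probes in place of 17738, and an adjusted p below 0.1 gave 48 and 39. Leaving out each array gave 6 to 173 higher and 14 to 277 lower, the lone array being assumed to vary like the others. With no background correction, no filter, a 2-fold minimum or the 4 arrays normalized alone, both counts stayed within 1.5 times. All 36 genes were also called when the 6 arrays were grouped by characteristics, with 1072 higher and 796 lower. That fit includes the 4 arrays on which the 36 genes were called, so it is not a separate check. Grouped by title, 0 and 0 were called (19 at an unadjusted p under 0.05). The cause of these differences was not tested.

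The replicate block on the description number gave 189 genes higher and 167 lower. Over the 4 arrays the paired deviations correlated at 0.514 in both pairs, which with 2 pairs is one value and too few to show a pairing, so it is not known whether the numbers pair the mice, and they are treated as sharing only a number. With the title number as the block, the title grouping called 0 and 0 (143 at an unadjusted p under 0.05). With the description number as the block, the characteristics grouping called 1650 and 1464. Correlations of the pairs were 0.7996, -0.00676 and 0.871 by title, paired by title number. By characteristics, paired by description number, they were 0.486, -0.119 and 0.465.

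Against 7 lists higher and 6 lower, camera with an estimated correlation gave 0 and 0, fry 0 and 0, and the title grouping with the title number as a block 11 lists higher. Leaving out an array gave 6 to 13 lists higher and 5 to 8 lower. Lymphoid and keratinocyte markers, and the genes Lrrc38, Mt2, Myh7, Aqp4 and Foxo3, left no tested value among probes detected on all 6 arrays. No named gene past the threshold changed direction under any alternative run, but every alternative reused arrays of the main comparison. The position of the array titled SKR_3 ranged from 1.08 to 1.16 and that of RXF_1 from -0.0297 to 0.0291, each moving by less than 0.0868, the pooled SD; on the axis built without each array they ranged from 0.991 to 1.16 and from -0.0205 to 0.102, with larger moves.

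The direction turned for values that had not passed. Myh4 was at 0.0901 under median scaling and 0.14 by title, with or without the block, and ranged from -0.25 to 0.0230 when an array was left out. Myh7 was at -0.0734 under median scaling and -0.0818 by title, with or without the block, ranging from -0.33 to 0.41. For lists, the direction is the one camera or fry gives, and the value is the median log2 change. The fatty acid oxidation list turned, with -0.00975 under median scaling, 0.11 over probes detected on all arrays, -0.10 for the mean of probes, 0.0295 both without the trend and in fry, -0.0519 by title and a range of -0.20 to 0.20 when an array was left out. By title, with or without the block, medians were 0.0237 for satellite cells, -0.13 for insulin, IGF and mTOR signalling and -0.23 for keratinocyte markers. Endothelial markers, at -0.21 there, passed as lower in both (adjusted p = 0.0366 and 0.0200, camera), against adjusted p-values up to 0.98 in other alternatives. The slow-fibre list was at 0.23 by characteristics, with or without the block. Endothelial markers were at -0.10 for the mean of probes, lymphoid markers at 0.0682 without the filter, and over probes detected on all arrays amino acid genes were at 0.14, smooth muscle markers at 0.13 and Schwann cell markers at 0.16. Leaving out an array gave medians of -0.00992 to 0.57 for fatty acid uptake, -0.14 to 0.61 for denervation, -0.29 to 0.19 for satellite cells, -0.88 to -0.16 for macrophage markers, 0.0311 to 0.15 for endothelial, 0.19 to 0.96 for Schwann cell, -0.31 to 0.0715 for lymphoid and -0.23 to 0.85 for keratinocyte markers.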

Other observations

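The 2 arrays with conflicting labels were assigned to no group in the main comparison. For Lcn2 the log2 intensity was 6.62 on the array titled RXF_1 and 12.48 on the array titled SKR_3, where the SKRC39 arrays had 5.93 and 6.37 and the RXF393 arrays 13.58 and 12.11. For Aqp4 the values were 11.11 and 6.14, against 11.35 and 11.16 on the SKRC39 arrays. For Igfbp5 they were 15.29 and 10.62, and for Ddit4 8.48 and 13.92. The array titled RXF_1 correlated at 0.980 across probes with SKRC39 replicate 1, and the array titled SKR_3 at 0.985 with RXF393 replicate 3. This measure did not follow the line among the concordant arrays either: RXF393 replicate 2 correlated at 0.926 and 0.937 with SKRC39 replicates 1 and 2, and at 0.896 with RXF393 replicate 3.

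Slow-fibre contractile genes varied widely between arrays, and as a list were lower in RXF393 when all 6 were grouped by title (adjusted p = 8.13e-07, camera; adjusted p = 0.56 with an estimated correlation) but not by characteristics (adjusted p = 0.82). The median of the list, relative to each gene's mean over the 6 arrays, was 1.08 and 0.59 on SKRC39 replicates 1 and 2, -0.14 and 0.90 on RXF393 replicates 2 and 3, -1.94 on the array titled RXF_1 and -0.08 on that titled SKR_3. Adipocyte markers were at -0.44 and 0.69 on the SKRC39 arrays, -0.22 and -0.55 on the RXF393 arrays, 0.95 on the array titled RXF_1 and -0.17 on that titled SKR_3.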
